A study of Mus musculus with 10 samples.

How the data were processed

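The hippocampus of 10 hMAPT mice was profiled by RNA sequencing, with 5 mice labelled control and 5 labelled AAV-circTau6 injection. Samples were taken 80 days after injection at 6 months of age. Per the labels' protocols, RNA integrity numbers were above 8.0, ribosomal RNA was removed, and strand-specific libraries were read as 150 bp pairs. The submitters' processing notes name StringTie 1.3.1 and RSEM with no role. The aligner, genome build and annotation are not given in the sources used here.

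Per the file headers, the authors deposited 1 table of 21956 genes with a count and a TPM (transcript abundance scaled to transcript length and library total) per gene and library, and the columns are unnormalised counts and TPM within each library. In the deposited counts, 108 entries had a count of 0 beside a TPM above 0, so the counts may be rounded estimates, and they were used as deposited. The deposited log2 fold change is the log2 ratio of the group means of TPM, as its values in the table show. The deposited p-value and FDR come from the authors' own comparison, whose test is not given in the sources used here. Gene symbols are those of the table, and 21804 IDs matched GENCODE release M21, built on GRCm38, of which 21403 are protein-coding. Coordinates are those of GRCm38, matched by gene ID, since the authors' build is not given.

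Total counts were 14762952 to 17647138 per library. At the shallowest library 3 counts equal 0.203 CPM, which covers counting error only. Groups were taken from the treatment label, and p-values measure the spread between 5 mice per group. All pairs of libraries differed by more than sampling noise.

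edgeR 4.0.16 in R 4.3.3 was the main test, chosen before the data were examined. Low genes were removed with filterByExpr, libraries scaled with TMM, and groups compared with the quasi-likelihood F test (robust fit), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the root of F. Of 53 gene lists written before the data were examined, 51 with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and an estimated correlation between genes. The others were the sex-linked list, a check of sex, and the T and NK cell list, with 2 members past the filter. Of the 51 lists, 0 were called with an estimated correlation, and 21 with a preset correlation of 0.01. Each list's mean level was also compared, outside the written plan, with an exact two-sided permutation test over all 252 sets of 5 libraries, whose smallest p is 0.00794.

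The genes named were fixed by a rule written before the data were examined. They are Mapt, called genes with a mean log2 CPM of at least 1, or, with fewer than 10 of these, the 20 lowest unadjusted p among genes at that level, up to 4 members of each described list by lowest p, and a panel of 14 genes. Any other gene is said to have been chosen after its values were seen; these are Map2, Cxcl9, Ddx3y, Alb, Gh, and list members beyond the first 4.

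Alternatives planned before the data were examined were DESeq2 1.42.0, limma voom with quality weights, other scalings and filters, a replicate block, 1 surrogate variable from sva 3.50.0, other thresholds, camera with a preset correlation, fry for a shift in 1 direction, and leaving out each library. Leaving out both libraries poor in choroid plexus transcripts, a choroid plexus covariate and a GC correction were added after the data were seen. On simulated counts for 14396 genes of this comparison, edgeR recovered 30% of genes changed 1.25-fold, 58% at 1.5-fold, 82% at 2-fold and 94% at 4-fold, with 7 false calls. DESeq2 recovered 36%, 62%, 84% and 96% with 25 false calls. Each gene was simulated independently, without the variation that genes share in the real libraries, so recovery and false calls may differ in the real data.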

Results

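RNA was measured in the hippocampus of 10 mice of the hMAPT genotype at 6 months of age. hMAPT mice carry the human gene for tau, a microtubule-binding protein of neurons. In 5 mice an adeno-associated virus (AAV, a gene delivery vector) carrying circTau6 had been injected 80 days earlier, and 5 mice were labelled control. The treatment label does not say what the control mice were given. By its title the series concerns circTau6, a circular RNA that comes from the tau gene, and the comparison asks which hippocampal transcripts differ when it is delivered. Total counts per library lay between 14762952 and 17647138, with a mean of 16066240 ± 1188746 (SD, n = 5) in control and 16640707 ± 1107184 (SD, n = 5) in circTau6 libraries. Y-linked transcripts such as Ddx3y were present in 10 of 10 libraries at 55.7 to 90.1 CPM, the count scaled to library size.

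No gene passed the edgeR test across all genes, and the lowest p-values belonged to Ctss and Ptprc, both with higher values after circTau6. Ctss, which encodes the lysosomal protease cathepsin S, had 67.2 CPM ± 6.67 (SD, n = 5) in control and 91.1 CPM ± 5.78 (SD, n = 5) in circTau6 libraries. Ptprc, which encodes the leukocyte surface protein CD45, had 4.64 CPM ± 1.26 (SD, n = 5) in control and 9.46 CPM ± 0.252 (SD, n = 5) in circTau6 libraries. For both genes 5 of 5 circTau6 libraries lay above every control library, and edgeR gave an adjusted p of 0.0713. Their log2 fold changes were 0.44 ± 0.07 (SE) for Ctss and 1.03 ± 0.16 (SE) for Ptprc. In GRCm38, Ctss (ENSMUSG00000038642) lies on chromosome 3 from 95526786 to 95556403, and Ptprc (ENSMUSG00000026395) on chromosome 1 from 138062861 to 138175708.

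Of 14396 genes tested with edgeR, 0 were higher and 0 were lower at an adjusted p under 0.05, while 637 had an unadjusted p under 0.05 against 720 that chance alone would give. Of these 637 genes, 371 had higher and 266 had lower values after circTau6. DESeq2, a second tool chosen before the data were examined, called 14 genes higher and 0 lower, and limma voom called 0, with 746 and 743 genes at an unadjusted p under 0.05. The 14 genes were Ptprc, Ctss, H2-K1, Mpeg1, Dock2, Adgre1, Cxcl9, C4b, C1qb, C1qc, H2-D1, Psmb8, C1qa and H2-T22. Of these, Cxcl9 was below the count filter of edgeR. The authors' deposited table has 8 genes with an FDR under 0.05, all higher after circTau6, and all 8 are among the 14 called by DESeq2. It gives a p under 0.05 for 672 genes, of which 636 are higher and 36 lower, a different balance from that of edgeR. Without circTau6 replicate 5, edgeR called 4 genes higher, and without control replicate 1 or without control replicate 3 it called 1.

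Because 0 genes passed, the 20 genes with the lowest unadjusted p among 12828 eligible genes, those with a mean log2 CPM of at least 1 and no predicted genes or pseudogenes, are given as values, and 19 of them had higher values after circTau6. They included microglial and macrophage genes: Mpeg1, a pore-forming protein of macrophages, with a log2 fold change of 0.39 ± 0.07 (SE), and Adgre1, the macrophage marker F4/80, with 0.71 ± 0.13 (SE). Dock2, a regulator of leukocyte migration, had 0.75 ± 0.14 (SE), Slc11a1, a phagosomal metal transporter, 0.94 ± 0.21 (SE), and Cd180, a Toll-like receptor homologue, 0.81 ± 0.19 (SE). Unc93b1, which carries Toll-like receptors to endosomes, had 0.38, the actin-bundling gene Lcp1 0.38, Arhgap30 0.65 and Arrdc2 0.55. The exception was Ugt8a, an enzyme of myelin galactolipid synthesis, at −0.27 ± 0.07 (SE), where 5 of 5 circTau6 libraries lay below every control. The edgeR adjusted p of these genes was 0.169 for Mpeg1, 0.173 for Adgre1 and Dock2, and higher for the others. Over all tested genes, 68 had every circTau6 library above every control and 53 had every one below, and chance gives 57 in each direction.

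**Figure D1:**
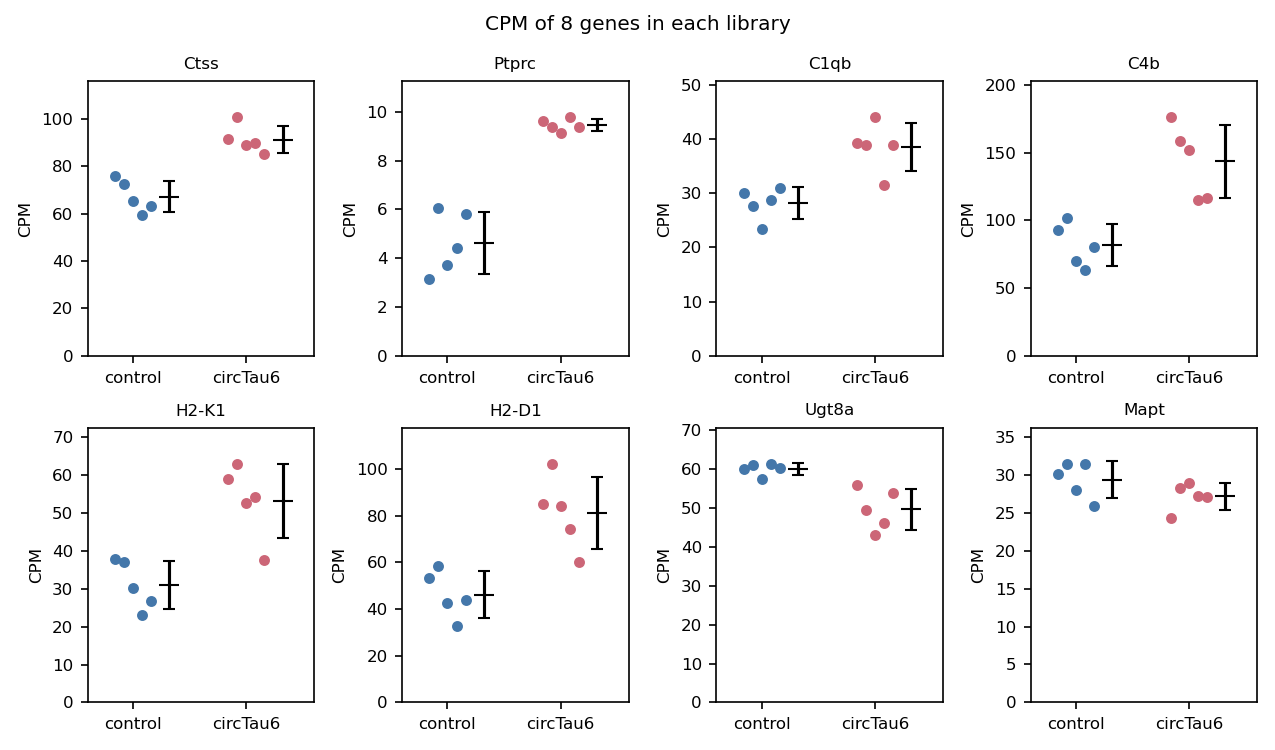
CPM of 8 genes in each library, with the groups on the horizontal axis; dots are single libraries, and the black mark with its bar is the mean and SD of 5 libraries. Every circTau6 library lies above every control for Ctss, Ptprc, C1qb, C4b and H2-D1 and below every control for Ugt8a, while the groups overlap for H2-K1 and Mapt.

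Genes of MHC class I presentation, which display peptides to cytotoxic T cells, had the largest share of members with a low p. All 14 measured members had positive log2 fold changes with a median of 0.78, and 12 passed the test adjusted over the list alone, against 0 of 14 over all genes tested. Among them were H2-T22 at 0.46 ± 0.10 (SE), the immunoproteasome subunit Psmb8 at 1.03 ± 0.23 (SE), H2-K1 at 0.78 ± 0.17 (SE) and H2-Q7 at 1.45 ± 0.36 (SE). The list was not called, with an adjusted p of 0.123 in camera with an estimated correlation. The mean level of the list was 2.79 ± 0.36 log2 CPM (SD, n = 5) in control and 3.60 ± 0.27 log2 CPM (SD, n = 5) in circTau6 libraries, with an exact two-sided permutation p of 0.0159 and 0.270 after Benjamini-Hochberg adjustment over 51 lists. H2 genes are close paralogs, so the authors' counting may have split reads between them.

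Genes of MHC class II presentation, used by macrophages and other antigen-presenting cells, had a median log2 fold change of 1.43. Of 7 measured members, 5 passed the test adjusted over the list alone and 0 over all genes tested, including H2-Aa at 3.02 times the control level, H2-Eb1 at a log2 fold change of 1.67 ± 0.48 (SE), H2-Ab1 at 1.51 ± 0.47 (SE) and the invariant chain Cd74 at 1.43 ± 0.44 (SE). The adjusted p in camera with an estimated correlation was 0.209. H2-Aa had 2.45 CPM in circTau6 replicate 5, below every control library, and 8.72 to 18.3 CPM in the other circTau6 libraries. Of 2 lists of other cells that can carry class II molecules, 0 were called, each with an adjusted p of 0.591 in camera with an estimated correlation. The B cell and plasma cell list had a median log2 fold change of 1.32 over 3 members. In circTau6 replicate 4 both this list, at 5.71 log2 CPM, and MHC class II presentation, at 2.99 log2 CPM, had their highest level. The 2 lists did not move together throughout. In circTau6 replicate 1 the B cell and plasma cell list had its lowest level, 1.64 log2 CPM. MHC class II presentation was at 2.22 log2 CPM there, above every control. In the list of border macrophages and monocytes, 0 of 6 members passed adjusted over the list alone. Ccr2, a chemokine receptor of monocytes, had 1.52 ± 0.60 (SE) at low levels, 0.39 CPM in control and 1.10 CPM in circTau6 libraries. Control replicate 4 had 1.34 CPM of Ccr2, and only 1 of 5 circTau6 libraries lay above every control. Without circTau6 replicate 5, 1 list was called, and it was MHC class II presentation, with an adjusted p of 0.0477 in camera with an estimated correlation.

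Complement genes, of the cascade that tags material for removal by phagocytes, had a median log2 fold change of 0.50. Of 12 measured members, 6 passed the test adjusted over the list alone and 0 over all genes tested. The C1q subunits C1qb, C1qc and C1qa had 0.45 ± 0.09 (SE), 0.37 ± 0.07 (SE) and 0.40 ± 0.09 (SE), and C4b had 0.81 ± 0.17 (SE). The list was not called, with an adjusted p of 0.178 in camera with an estimated correlation.

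Homeostatic microglia markers had smaller differences, with a median log2 fold change of 0.09 over 12 members. Of these, 2 passed the test adjusted over the list alone and 0 over all genes tested: the growth factor receptor Csf1r at 0.17 ± 0.06 (SE) and Tmem119 at 0.25 ± 0.08 (SE). The adjusted p in camera with an estimated correlation was 0.123. Among disease-associated microglia genes, 0 of 21 passed adjusted over the list alone, and 19 of 21 had a positive sign. Tyrobp, the adaptor of Trem2, had 0.41 ± 0.13 (SE), Trem2 0.27 ± 0.13 (SE) and Cd68 0.25 ± 0.12 (SE), with an adjusted p of 0.483 for the list in camera with an estimated correlation. Aif1, the microglial marker IBA1, had 0.51 ± 0.23 (SE).

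In the list of neurotoxic-type reactive astrocytes, 5 of 11 members passed the test adjusted over the list alone and 0 over all genes tested, and 3 of these 5 (Psmb8, H2-D1 and H2-T23) act in MHC class I presentation. The others were Ggta1 at 0.42 ± 0.16 (SE) and Iigp1 at 0.89 ± 0.32 (SE), and the adjusted p was 0.243 in camera with an estimated correlation. Gfap, the intermediate filament of astrocytes, had 0.26 ± 0.13 (SE) and Serpina3n 0.05 ± 0.09 (SE). All 24 interferon response genes had positive log2 fold changes with a median of 0.42, 0 passed adjusted over the list alone, and the adjusted p was 0.507 with an estimated correlation of 0.796 between members. Isg15 had 0.95 ± 0.32 (SE).

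**Figure D2:**
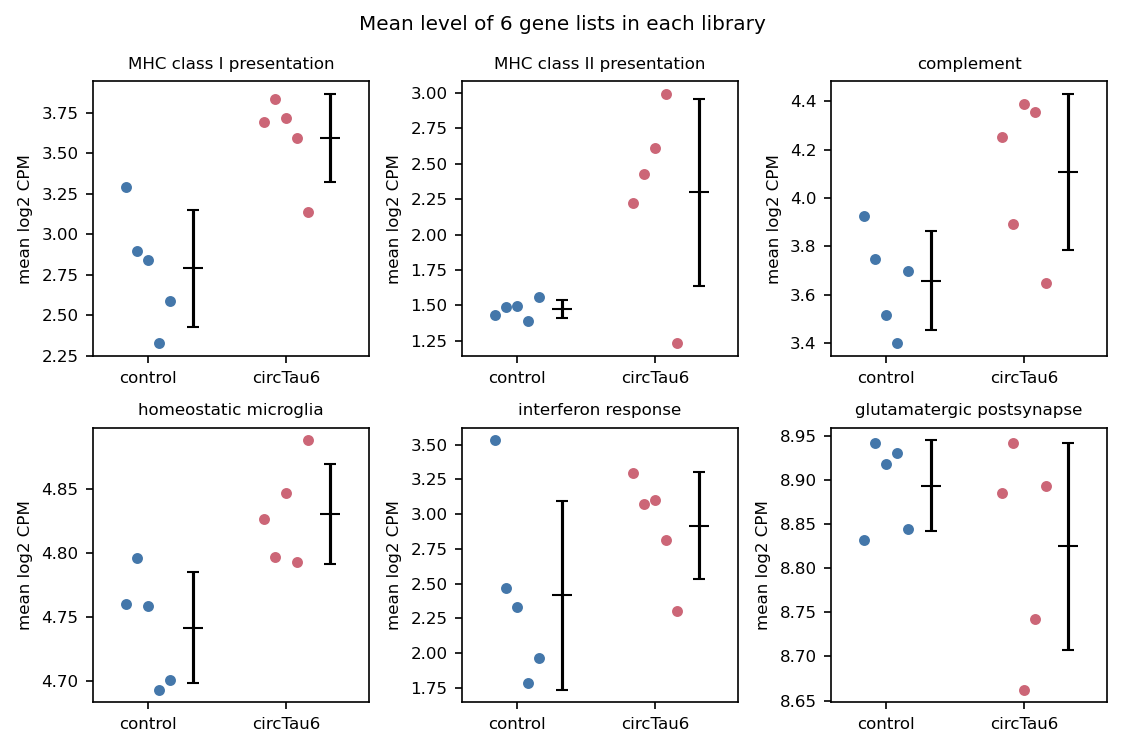
Mean log2 CPM of 6 gene lists in each library, with the groups on the horizontal axis; dots are single libraries, and the black mark with its bar is the mean and SD of 5 libraries. For MHC class I presentation 4 of 5 circTau6 libraries lie above every control, and for interferon response the groups overlap, with the highest value of 3.53 in control replicate 1.

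Choroid plexus transcripts, which come from the tissue beside the hippocampus that makes cerebrospinal fluid, were nearly lacking in 1 library of each group. Ttr, the transthyretin gene, had 650 counts in control replicate 2 and 411 counts in circTau6 replicate 5, against 28538 to 86422 counts in the other libraries. The group difference in Ttr was 0.11 ± 1.21 (SE) on the log2 scale with an edgeR adjusted p of 0.996. The choroid plexus list was not called, with an adjusted p of 0.942 in camera with an estimated correlation. The same circTau6 replicate 5 had the lowest MHC class II level. Control replicate 2, also poor in choroid plexus transcripts, had a class II level of 1.49 log2 CPM, within the control range of 1.39 to 1.56. With both libraries left out edgeR called 3 genes higher after circTau6, Ctss, Ptprc and H2-Aa.

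**Figure D3:**
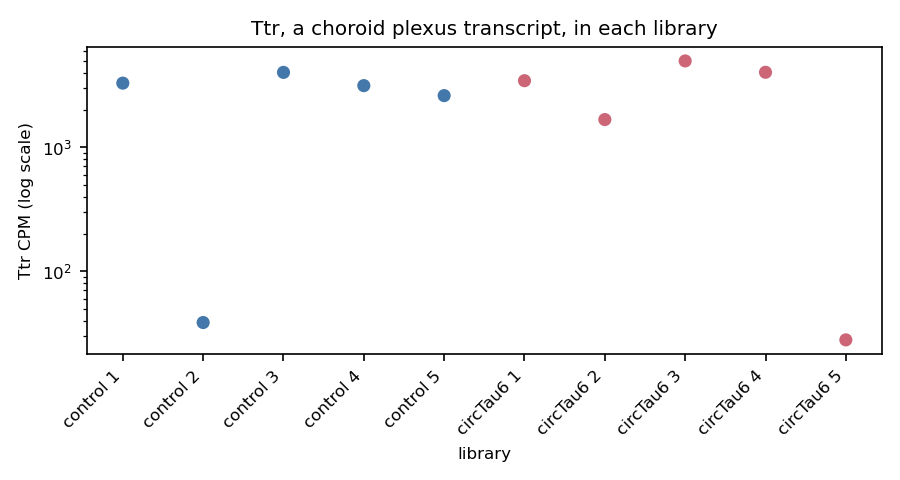
CPM of Ttr on a logarithmic axis in each library, named on the horizontal axis; each point is 1 library, blue for control and red for circTau6. Control replicate 2 and circTau6 replicate 5 lie far below the other libraries, which range from 1671 to 4961 CPM.

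Neuronal lists had small differences, and none was called by camera with an estimated correlation. Glutamatergic postsynapse genes had a median log2 fold change of −0.05 over 16 members, with an adjusted p of 0.591 in camera with an estimated correlation. Presynaptic vesicle release genes had a median of −0.04 over 18 members and the same adjusted p in camera. With the preset correlation, camera called both lists lower, with adjusted p of 0.00366 and 0.00895, and among other lists GABA and glycine receptors at 0.00066 and voltage-gated ion channels at 0.00176. With an estimated correlation the adjusted p of these last lists was 0.507 and 0.591. All 4 lists were lowest in circTau6 replicate 3, which stood apart: its deviations from the mean of the libraries correlated with transcript GC content at 0.40, against −0.11 to 0 in the others, and the preset test was not repeated without it. Syp, a synaptic vesicle protein, had −0.05 ± 0.04 (SE), Snap25, a membrane fusion protein, −0.05 ± 0.05 (SE), and the postsynaptic scaffold gene Dlg4 −0.01 ± 0.04 (SE). The activity-dependent genes Fos and Arc had 0.61 ± 0.41 (SE) and 0.05 ± 0.26 (SE). In the myelinating oligodendrocyte list, 1 of 13 members passed adjusted over the list alone, the gene Ugt8a, and Mbp had 0.01 ± 0.05 (SE).

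Mapt, the mouse tau gene (ENSMUSG00000018411, chromosome 11 from 104231390 to 104332090 in GRCm38), was read first in each library and had 387 to 530 counts. Its level was 29.3 CPM ± 2.42 (SD, n = 5) in control and 27.2 CPM ± 1.75 (SD, n = 5) in circTau6 libraries, a log2 fold change of −0.11 ± 0.07 (SE) with an edgeR adjusted p of 0.981. Map2, another microtubule-associated gene of neurons, had at least 21414 counts in every library. In control libraries the mean was 13.8 TPM for Mapt and 841 TPM for Map2. Whether the Mapt row holds all tau transcripts of these mice cannot be told, so its values do not show that total tau RNA was unchanged. Human and mouse tau reads cannot be told apart in this table, and circTau6 itself has no row of its own, so its level was not analysed here.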

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

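The tests of explanations and the counts over splits in this part were chosen after the result was seen; the DESeq2, edgeR and camera calls they refer to were chosen before the data were examined.

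The mean log2 CPM of the choroid plexus list was 1.02 in control replicate 2, where the other controls had 5.37 to 5.96, and 0.89 in circTau6 replicate 5, where the others had 4.65 to 6.07. Each library lay far from the others of its own group; 100 groups of values were examined, and chance picks out about 5 in 100. Ttr, the transthyretin gene of the choroid plexus, had 650 and 411 counts in these libraries and at least 28538 in each of the others. For 13 of 13 markers both libraries were the lowest of their own group. Lower depth is argued against, since the shallower of the 2 held 98.1% as many counts as the shallowest other library. The amount of choroid plexus tissue in the samples was not tested separately from these markers, and no biological explanation was tested.

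The 14 genes DESeq2 called all had higher values after circTau6, and 5 of them lie in the MHC region of chromosome 17, between 33996017 and 36042747 in GRCm38. A variant of that region carried by some animals cannot be told apart from a response. The H2 genes, C4b, C2, Cfb, Psmb8, Psmb9, Tap1, Tap2 and Aif1 were set aside, called or not. The region's 60 other tested genes had a median log2 fold change of 0.0475. This median does not cover the genes set aside, and uncalled ones such as H2-Aa and H2-T23 also had higher values. A variant could also act on a few genes alone, or on genes elsewhere. Choroid plexus tissue is argued against as the cause by the like levels of its list in the groups. These were 4.73 ± 2.09 log2 CPM (SD, n = 5) in control and 4.64 ± 2.17 log2 CPM (SD, n = 5) in circTau6 libraries. With levels so alike, the choroid plexus covariate could hardly change the group difference and adds no test. The median over the 13 genes tested by edgeR was 0.71 both without and with it. A higher number of unchanged microglia was not decided by the test made. Of 12 homeostatic markers, 11 lay more than 2 SE below 0.372, the smallest change in the set. A set chosen by its calls overstates its own changes, and no homeostatic marker was in it. The outcome was thus nearly fixed by the choice of the set, and the error of the smallest change was not counted. The summed homeostatic markers were 1.10 times the control level, so a rise in microglia of about that size stays open. An effect of the delivered circTau6, of the vector, and of differences between animals or cages stay open and untested.

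Chance was not excluded for the DESeq2 calls. DESeq2 called 14 genes, and 6 of 60 splits of the 10 libraries into groups of 5, the real one counted here and below, gave as many, the highest other split giving 117. Another split gave 96, and the choroid-poor libraries were on the same side in the first and apart in the second. Such counts point to a structure of the samples whose source was not tested. The split with 117 set apart control replicates 1 and 5 and circTau6 replicates 1, 3 and 4. These libraries had the highest levels of the meningeal fibroblast list, 4.13 to 5.05 log2 CPM against 3.22 to 3.87 in the others. The split with 96 held circTau6 replicate 5, at 3.47, in place of replicate 1. The meningeal list was singled out after the split was seen and is not particular to it. Endothelial cells, at 4.388 to 4.69 against 4.165 to 4.341 log2 CPM, also separated the split with 117 completely. So did NRF2 targets and the list of extracellular matrix and scar. Between control and circTau6 the meningeal list was not called, with an adjusted p of 0.875 in camera with an estimated correlation. For the 0 genes and 0 lists called by edgeR and camera the count of splits decides nothing, since 100 of 100 splits reach 0; the highest others were 45 genes and 1 list. For the 637 genes with an unadjusted p under 0.05, 35 of 100 splits gave as many, and the highest other gave 2241. MHC class I presentation had 12 members with an unadjusted p under 0.05, and 3 of 100 splits gave as many for this list, the highest other giving 13. That list was singled out after its values were seen. A further count took in each split the largest share of such members over the lists with at least 10 tested members. Smaller lists did not compete. The real split had 85.7%, and the highest other was 100%. Of 100 splits, drawn from 126 distinct ones, 5 gave as large a share, the real one and 4 others. This is right at the limit of 0.05, so chance was not excluded once the choice among these lists was counted.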

How the results depend on the processing

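The 3 alternatives on choroid plexus and GC content were added after the data were seen. The number of genes higher in circTau6, 0 with edgeR as planned, was 2 with no low-count filter, 4 with the replicate block, 14 with DESeq2, 2 at an adjusted p under 0.1, 2 with 1 surrogate variable, 3 with both choroid-poor libraries left out, and 2 with the choroid plexus level as covariate. Leaving out single libraries gave 0 to 4 genes higher in circTau6, with 4 without circTau6 replicate 5 and 1 without control replicate 1 or control replicate 3. Genes lower in circTau6 stayed at 0 in every alternative run. Gene list calls were 0, against 21 with the preset correlation in camera, 0 with fry for a shift in 1 direction (lowest adjusted p 0.0754), and 0 to 1 when single libraries were left out. fry for change in either direction, which was not planned and compares a list with no other genes, gave an adjusted p under 0.05 for 5 lists: 0.0198 for MHC class I presentation, complement and neurotoxic-type reactive astrocytes, 0.0343 for homeostatic microglia and 0.0404 for inflammatory cytokines. The cause of these changes was not tested, except that a looser threshold admits more genes.

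Of 48 single genes followed, 43 kept their sign in all alternatives. The others had values near 0 or wide errors and were not called. Ttr was −0.034 with limma voom and −0.008 with 1 surrogate variable, Mbp was −0.007 with limma voom, −0.021 with both choroid-poor libraries left out and −0.015 with the GC correction, and Arc was −0.13 with both choroid-poor libraries left out. Leaving out single libraries gave −0.21 to 0.43 for Ttr, −0.028 to 0.049 for Mbp, −0.18 to 0.17 for Arc, −0.031 to 0.099 for Serpina3n and −0.027 to 0.002 for Dlg4. The choroid plexus list changed direction with the GC correction, at an adjusted p of 0.954, and in 5 of the 10 fits with a single library left out, and its adjusted p in camera lay between 0.589 and 0.997 in those 10 fits; the cause was not tested.

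No label says that the replicate numbers pair animals. Each gene's deviation from the mean of its group was taken in each library. Over all tested genes, these deviations correlated between same-numbered libraries at 0.10, 0.13, 0.14, −0.06 and −0.08. By these deviations, no control library correlated best with the circTau6 library of its own number. Such correlations also carry differences in tissue, with 0.576 between the choroid-poor control replicate 2 and circTau6 replicate 5. A pairing is therefore not excluded. With the replicate block edgeR called 4 genes: Ctss, H2-K1 and H2-D1 with an adjusted p of 0.0229, and C4b with 0.0128.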

Other observations

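The sums over lists and the pathway tests in this part were chosen after values were seen, as were the genes Cxcl9, Alb and Gh; the camera tests of the lists were chosen before the data were examined.

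Transcripts of T and NK cells were scarce, and the T and NK cell list had only 2 of 15 members past the count filter. Summed over its members, the list had 39 to 86 counts per control library and 72 to 172 per circTau6 library. This is 3.58 CPM ± 1.41 (SD, n = 5) against 7.15 CPM ± 1.86 (SD, n = 5), with an exact two-sided permutation p of 0.0159. The same sum was taken for all 52 lists, and 0 passed Benjamini-Hochberg adjustment, with an adjusted p of 0.165 for this list. The complement sum was 1.46 times and the homeostatic microglia sum 1.10 times the control level, each with 5 of 5 circTau6 libraries above every control. Both had an exact two-sided permutation p of 0.00794, the smallest the design allows, and the same adjusted p of 0.165. A sum is weighted to abundant members; by the mean log2 CPM, 3 of 5 circTau6 libraries lay above every control for complement (exact permutation p 0.0556) and 4 of 5 for homeostatic microglia (0.0159). Cxcl9, a chemokine that attracts T cells, had 0.271 CPM ± 0.203 (SD, n = 5) in control and 1.83 CPM ± 1.01 (SD, n = 5) in circTau6 libraries. It was below the count filter of edgeR. Its counts overlapped between the groups, with 1 to 9 in control libraries and 7 to 55 in circTau6 libraries. Cst7, a disease-associated microglia gene below the count filter, had 0.218 CPM ± 0.180 (SD, n = 5) against 0.716 CPM ± 0.188 (SD, n = 5).

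Ribosomal protein genes had positive log2 fold changes in 36 of 37 members with a median of 0.07, and 13 of 13 mitochondrially encoded respiratory chain genes had negative ones with a median of −0.06. Neither list was called, with adjusted p of 0.378 and 0.483 in camera with an estimated correlation. The highest ribosomal level, 6.76 log2 CPM, and the lowest mitochondrial level, 11.88 log2 CPM, were both in circTau6 replicate 3, the library that stood apart in GC content. Mitochondrial transcripts took 10.17% ± 0.12 (SD, n = 5) of counts in control and 9.83% ± 0.19 (SD, n = 5) in circTau6 libraries.

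Of 320 pathways of the deposited table with 10 to 300 tested genes, 0 were called by camera with an estimated correlation and 27 with the preset correlation. Transcripts of other tissues varied between single libraries: Alb, the liver gene for albumin, had 241 to 3690 counts over the 10 libraries, and Gh, the pituitary gene for growth hormone, 2 to 291.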
